A study of Homo sapiens with 9 samples.

How the data were processed

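RNA of the human skin fibroblast line HA-HSF was sequenced in 9 libraries, 3 each for cells treated with exosome-like nanoparticles of Panax notoginseng (exosome), H2O2 or PBS. The molecule is labelled total RNA and the libraries are described as mRNA libraries made with a standard Illumina protocol. The protocol text also speaks of transfection and of DCs, which do not match the rest of the labels, and it gives no dose or time. The authors deposited a table of raw read counts per gene and a table of FPKM (fragments per kilobase of gene length, scaled to the library total). Per the labels the authors used HISAT2 and StringTie, with no versions, and neither the genome build nor the annotation is stated. Of 58542 gene identifiers shared with GENCODE 29 on GRCh38, 48237 (82.4%) have the same start and end, so positions are given on that build. The deposited count table holds 61330 features with their gene length in bases as the authors give it, of which 713 have no gene name. In the deposited FPKM table every column equals count divided by gene length and by 1 constant per library, which exceeds that library's total count by 0.313% to 3.37%.

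Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Total counts ran from 13438300 to 20864811 per library. Genes were kept by filterByExpr with its defaults, which left 16627, and libraries were scaled with TMM factors, which lay between 0.971 and 1.03. All 9 libraries entered 1 fit with a mean per group and 6 residual degrees of freedom, and each pair of groups was compared with the robust quasi-likelihood F test. The biological coefficient of variation was 0.0730. Genes passed at a Benjamini-Hochberg adjusted p of 0.05 over all genes tested. Exosome was compared with PBS, H2O2 with PBS and exosome with H2O2. Shares of mitochondrial and long non-coding reads were compared by an exact permutation test, two-sided.

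The test, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The 33 lists cover fibrillar and network collagens, matrix glycoproteins with proteoglycans and elastic fibre, hyaluronan with collagen processing and crosslinking, matrix metalloproteinases and inhibitors, TGF-beta targets and myofibroblast genes, and fibroblast identity. They further cover NRF2 targets, peroxide and superoxide removal enzymes, p53 targets, DNA repair, G2 and M phase, G1/S and DNA replication, senescence and its secretome, NF-kB inflammatory genes, type I interferon-stimulated genes, immediate early and serum response, and growth factors and wound repair. ATF4 and integrated stress response, endoplasmic reticulum chaperones, heat shock chaperones, cholesterol and fatty acid synthesis, glycolysis and hypoxia, nuclear-encoded respiratory chain, mitochondrially encoded genes, lysosome and autophagy, ribosomal proteins, replication-dependent histones and nuclear long non-coding RNAs were also listed. Markers of keratinocytes, dendritic and other immune cells, endothelium, melanocytes, and pericytes with smooth muscle stood for other cells. Some genes are on more than 1 list, such as CXCL8 under NF-kB and senescence.

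Lists with at least 5 tested members, 32 of the 33, were tested with camera at its preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. The tool fry was run as an alternative; it tests whether a list's genes move on balance 1 way, without setting the list against other genes. Named genes were, for each comparison, the 8 largest increases and 8 largest decreases. These had to pass, have a mean of at least 5 CPM and libraries that did not overlap between the groups, leaving out genes without a symbol, pseudogenes, genes of the Y chromosome and XIST. The 4 members with the smallest p of each list that passed or had at least 3 changed members were added, and from each other list the 1 member with the smallest p. This gave 242 distinct genes, from which the text takes its examples. For genes with 1 to 3 counts in a group the ratio is given with its 95% exact counting interval, which covers counting error only.

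Alternatives were DESeq2 1.42.0 size factors and its Wald test, upper-quartile factors, library totals alone, no filter and a filter of 50 counts in 3 libraries, limma-voom, the 6 libraries of each comparison alone, the replicate number as a block, leaving out each library, the FPKM values in limma-trend with pseudocounts of 1 and 0.1 and without a filter, a fold of at least 2, and protein-coding nuclear genes alone. After the data had been seen, leaving out the mitochondrial genes before scaling and correcting GC content and gene length per library were added. Genes shared by exosome and H2O2 against PBS were set against 20 simulations of unchanged groups with the same PBS libraries, since 3 controls cannot be split into parts of at least 2. Group labels were also exchanged in all 10 splits of each 6 libraries, and in 50 drawn splits of the 9.

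The gene test was tested on simulated data with the depths and spread of these libraries, and genes that the filter of a run removed were counted as not called. For exosome against PBS it recovered 43 of 67 genes changed 1.5-fold, 56 of 67 changed 2-fold and 65 of 66 changed 4-fold, and called 11 of 16427 unchanged genes. For H2O2 against PBS these were 50, 60 and 64, with 22 unchanged genes called, and for exosome against H2O2 53, 52 and 66, with 15 called. In each run unchanged genes made up a larger share of the called genes than the threshold of 0.05. Few genes were changed in these simulations, and all groups had the same mitochondrial share. They therefore do not cover the exosome comparisons, where 75.2% of genes passed against PBS. Membrane and signal segments were predicted from annotated protein sequences by hydropathy, as a mean of at least 1.6 over 19 residues anywhere or at least 2 over 10 residues within the first 35. The rule was checked on proteins of known location, finding 20 of 20 membrane or secreted ones and 2 of 20 others. Tables, permutation tests and figures were made in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. No library was left out.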

Results

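RNA sequencing of HA-HSF, a human skin fibroblast line bought from a cell bank, was compared between 3 groups of 3 libraries. The groups had received exosome-like nanoparticles from Panax notoginseng (a medicinal root, here called exosome), hydrogen peroxide (H2O2, an oxidant) or phosphate-buffered saline (PBS, the buffer control). Doses and times of treatment were not stated, nor whether the exosome cells had also received H2O2. The total count per library ran from 17199209 to 18745118 in PBS, from 16196449 to 20864811 in H2O2 and from 13438300 to 17906831 in exosome (n = 3 each). Of 61330 features in the count table, 16627 passed the low-count filter and were tested. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries. Expression is given in CPM, read counts relative to library size with scaling factors applied (mean ± SD over 3 libraries), log2 fold changes as estimate ± standard error, and positions on the GRCh38 genome.

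The comparison of exosome with PBS asked how fibroblasts given the plant particles differed from those given the buffer. Reads from the mitochondrial genome took 35.9% ± 0.321 of the counts in the exosome libraries and 4.59% ± 0.191 in the PBS libraries. Genes for the extracellular matrix that fibroblasts make were lower: fibronectin, FN1 (ENSG00000115414, chromosome 2, 215360440 to 215436073), fell 9.89-fold, from 5601 ± 330.3 to 567 ± 23.96 CPM. Most NF-kB inflammatory genes and immediate early genes were higher, and CXCL2, which encodes an attractant of neutrophils (ENSG00000081041, chromosome 4, 74097040 to 74099196), rose from 9.22 ± 1.15 to 239 ± 7.68 CPM. Interferon-stimulated antiviral genes and genes for cholesterol synthesis, lysosomes and chaperones of the endoplasmic reticulum were lower in the exosome libraries.

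All 13 measured mRNAs of the list of mitochondrially encoded genes rose in exosome against PBS, with a median log2 fold change of 2.89. They code for subunits of the respiratory chain and ATP synthase. As a list they had a camera adjusted p of 4.64e-45, and of 9.93e-04 with an estimated correlation. MT-CO2, a subunit of cytochrome c oxidase (ENSG00000198712, chromosome MT, 7586 to 8269), rose from 4395 ± 156 to 32480 ± 418 CPM (log2 fold change 2.89 ± 0.04, adjusted p = 1.59e-34). MT-ND2 rose by 3.06 ± 0.05 and MT-ATP6, which overlaps its neighbours MT-ATP8 and MT-CO3, by 2.68 ± 0.04 on the log2 scale. Relative to all nuclear reads, mitochondrial reads were 11.7 times as abundant as in PBS (exact permutation test, p = 0.1, two-sided, the smallest value that 3 against 3 libraries allow). Nuclear genes for the same respiratory chain did not pass as a list (adjusted p = 0.706): 11 of 38 rose, 15 fell and 12 did not pass. ATP5F1A, a subunit of ATP synthase, fell from 427 ± 9.36 to 155 ± 6.67 CPM. Reads of long non-coding RNA genes took 1.53% ± 0.0233 of the exosome counts and 0.710% ± 0.00646 of the PBS counts, and 1462 of the 2139 such genes tested rose while 101 fell. On the list of nuclear long non-coding RNAs, kept as a sign of RNA quality, 12 of 14 rose and 2 fell (adjusted p = 1.47e-08). NEAT1, a scaffold of nuclear paraspeckles (ENSG00000245532, chromosome 11, 65422774 to 65445540), rose from 168 ± 3.44 to 2025 ± 55.5 CPM, and NORAD, a cytoplasmic RNA on the same list, fell from 604 ± 13.4 to 211 ± 2.65 CPM.

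**Figure D1:**
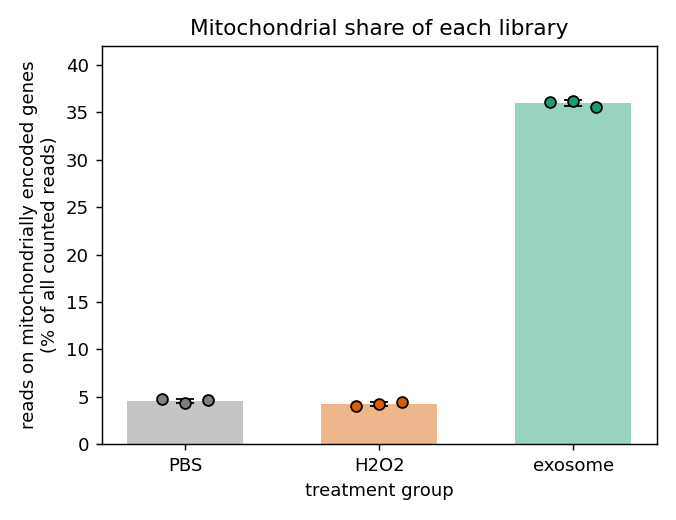
Share of each library's counted reads that fell on mitochondrially encoded genes, in percent of the library total without scaling factors, for PBS, H2O2 and exosome. Bars are means of 3 libraries, error bars are SD and points are libraries; the exosome libraries lie between 35.6% and 36.2%, and those of PBS and H2O2 between 4.07% and 4.75%.

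Among matrix glycoproteins, proteoglycans and elastic fibre genes 26 of 28 fell and 2 rose, with a median log2 fold change of -2.15. The camera adjusted p was 2.48e-37, and 0.00632 with an estimated correlation. Tenascin, TNC, fell from 3360 ± 137 to 389 ± 15.6 CPM, and LAMC1, a laminin chain of basement membranes, from 1369 ± 57.8 to 232 ± 3.51 CPM. Of 20 fibrillar and network collagens 17 fell and 3 rose (median -1.37, adjusted p = 1.50e-08, against adjusted p = 0.169 with an estimated correlation). COL1A2, a chain of type I collagen, fell from 7817 ± 117 to 1837 ± 11.03 CPM, and COL12A1 fell 9.93-fold. Enzymes of hyaluronan synthesis and collagen processing fell in 16 of 20 members, 2 rose and 2 did not pass (adjusted p = 3.06e-15). LOX, lysyl oxidase, which crosslinks collagen and elastin (ENSG00000113083, chromosome 5, 122063195 to 122078360), fell 13.1-fold, from 1241 ± 49.99 to 94.96 ± 1.32 CPM (log2 fold change -3.71 ± 0.05, adjusted p = 6.30e-36). Of the metalloproteinases that degrade matrix and their inhibitors, 12 of 15 fell, 1 rose and 2 did not pass (adjusted p = 8.89e-09). MMP3 fell from 1606 ± 17.8 to 190.1 ± 1.88 CPM and the inhibitor TIMP2 from 3670 ± 95.7 to 842 ± 1.85 CPM. TGF-beta targets and myofibroblast genes fell in 15 of 22 cases, with 4 higher and 3 not passing (adjusted p = 4.78e-06), and the receptor TGFBR2 fell from 686 ± 8.23 to 178 ± 3.73 CPM. Fibroblast identity genes fell in 14 of 18, 1 rose and 3 did not pass (adjusted p = 3.08e-13), with DPP4 going from 656 ± 19.6 to 148 ± 1.97 CPM.

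The secretory route and lipid synthesis moved the same way. Of 20 genes for endoplasmic reticulum chaperones and the unfolded protein response, 16 fell, 2 rose and 2 did not pass (median -1.66, adjusted p = 1.07e-13). HSPA5, the main chaperone there, fell from 1021 ± 15.9 to 183 ± 7.27 CPM. Cholesterol and fatty acid synthesis fell in 27 of 28 genes and 1 rose (adjusted p = 1.00e-17). DHCR7, which makes the last step to cholesterol, fell 10.99-fold, SCD, which desaturates fatty acids, fell 7.53-fold, and SREBF2, the regulator of sterol genes, fell 4.53-fold. Lysosome and autophagy genes fell in 25 of 31, 2 rose and 4 did not pass (adjusted p = 9.76e-18), with LAMP1 going from 869.5 ± 20.3 to 166 ± 2.64 CPM. Peroxide and superoxide removal enzymes fell in 16 of 21, 3 rose and 2 did not pass (adjusted p = 4.15e-04). CAT, catalase, fell from 90.7 ± 3.21 to 29.4 ± 1.105 CPM. Of 27 targets of NRF2, the regulator of the antioxidant response, 18 fell, 6 rose and 3 did not pass (adjusted p = 0.0449, against adjusted p = 0.0946 with an estimated correlation). That call was lost with upper-quartile scaling (adjusted p = 0.123) and without exosome replicate 2 (adjusted p = 0.0509). HMOX1, heme oxygenase, rose from 68.7 ± 2.29 to 189.9 ± 11.5 CPM, while the cystine transporter SLC7A11 fell from 117 ± 6.49 to 33 ± 2.07 CPM. Heat shock chaperones fell in 14 of 17, 2 rose and 1 did not pass (adjusted p = 0.00798, against adjusted p = 0.111 with an estimated correlation). Cell cycle genes of G2 and M phase fell in 26 of 29, 2 rose and 1 did not pass (adjusted p = 2.56e-05, against adjusted p = 0.0978 with an estimated correlation). TOP2A, a topoisomerase of dividing cells, fell from 192 ± 6.94 to 56.3 ± 4.805 CPM.

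Inflammatory and early response genes rose. Of 33 NF-kB inflammatory genes 25 rose, 5 fell and 3 did not pass (adjusted over the list alone, 25 rose and 6 fell), with a median log2 fold change of 1.75 (adjusted p = 3.22e-15). CXCL8, interleukin 8, rose from 93.7 ± 3.81 to 637 ± 35.4 CPM, and NFKBIA, the inhibitor of NF-kB, from 67.5 ± 3.405 to 374 ± 6.46 CPM. Immediate early and serum response genes rose in 32 of 33 cases and 1 fell (adjusted p = 4.86e-17). FOS rose from 80.3 ± 3.401 to 514 ± 16.9 CPM, JUN from 314 ± 1.96 to 1394 ± 47.6 CPM, and the stress factor ATF3 from 2.87 ± 0.1895 to 75.5 ± 3.47 CPM. Type I interferon-stimulated genes fell in 26 of 32, 1 rose and 5 did not pass (median -1.86, adjusted p = 6.65e-26). MX1, an antiviral GTPase, fell 5.32-fold. Replication-dependent histones, whose mRNAs mostly end without a poly(A) tail, rose in 15 of 18, 1 fell and 2 did not pass (adjusted p = 8.03e-04). HIST1H2BG, from a family of near-identical copies, rose from 4.49 ± 0.543 to 43.5 ± 1.72 CPM, and HIST1H2BK fell from 88.7 ± 2.83 to 45.2 ± 1.87 CPM.

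The remaining lists did not pass camera in exosome against PBS. With fry, which does not set a list against other genes, G1/S, senescence, glycolysis and hypoxia, nuclear-encoded respiratory chain, DNA repair, growth factors and markers of endothelium and pericytes passed downward and immune markers upward (adjusted p at most 0.00157). For ATF4 and integrated stress response genes 8 of 24 rose and 12 fell (adjusted over the list alone, 9 and 13; adjusted p = 0.662), with a negative median of -0.42 where the test pointed up. ATF4 itself rose from 205 ± 11.2 to 675 ± 21.3 CPM, and PSAT1, of serine synthesis, fell from 69.8 ± 2.98 to 15.2 ± 1.56 CPM. Of 28 p53 targets 9 rose and 12 fell (adjusted p = 0.796), with a median of -0.10 (0.13 with upper-quartile scaling) where the test pointed up. GADD45A rose from 106 ± 4.505 to 362 ± 3.23 CPM and ZMAT3 fell from 272 ± 7.404 to 85.6 ± 2.01 CPM. Senescence genes split, 15 of 33 rising and 16 falling (adjusted p = 0.8402), with a median of 0.03 (-0.04 with library totals as the scaling) and a mean of 0.23 where the test pointed down. Glycolysis and hypoxia genes fell in 20 of 29 and 8 rose (adjusted p = 0.0513). That list passed downward when any 1 PBS library, any 1 H2O2 library or exosome replicate 1 was left out (adjusted p = 0.0258 to 0.0492), with library totals as the scaling (0.0352), with mitochondrial genes left out (0.0474) and with GC content and gene length corrected (0.00655). PGK1 fell from 459 ± 7.01 to 133 ± 3.79 CPM and ADM rose from 246 ± 12.5 to 865 ± 6.59 CPM. For G1/S and DNA replication genes 16 of 30 fell and 9 rose (adjusted over the list alone, 17 and 9; adjusted p = 0.198). DNA repair genes fell in 14 of 31 and rose in 10 (adjusted p = 0.652), growth factors fell in 14 of 28 and rose in 11 (adjusted p = 0.302), and ribosomal proteins rose in 20 of 47 and fell in 17 (adjusted p = 0.805). With upper-quartile scaling more members rose than fell among the nuclear-encoded respiratory chain (20 and 7), p53 targets (14 and 11), G1/S (12 and 11), DNA repair (11 and 10), senescence (17 and 14) and ribosomal proteins (30 and 10). With library totals as the scaling 18 ribosomal protein genes rose and 19 fell, and with GC content and gene length corrected 14 and 24. VEGFA, the vascular growth factor, rose from 24.8 ± 0.732 to 106 ± 1.24 CPM. Unless stated, counts adjusted over the list alone were the same as those over all genes. Markers of other cells did not pass as lists: keratinocyte (2 of 8 rose, 2 fell, adjusted p = 0.961), dendritic and other immune (3 of 5 rose, 2 fell, adjusted p = 0.392), endothelial (1 of 7 rose, 4 fell, adjusted p = 0.652) and pericyte and smooth muscle (4 of 6 fell, adjusted p = 0.185). CCR7, a chemokine receptor on the immune list, rose from 1.61 ± 0.2096 to 20.4 ± 1.29 CPM. The melanocyte list had 4 measured members, too few for a test, of which 2 fell, MITF going from 35.6 ± 3.51 to 15.6 ± 1.39 CPM.

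**Figure D2:**
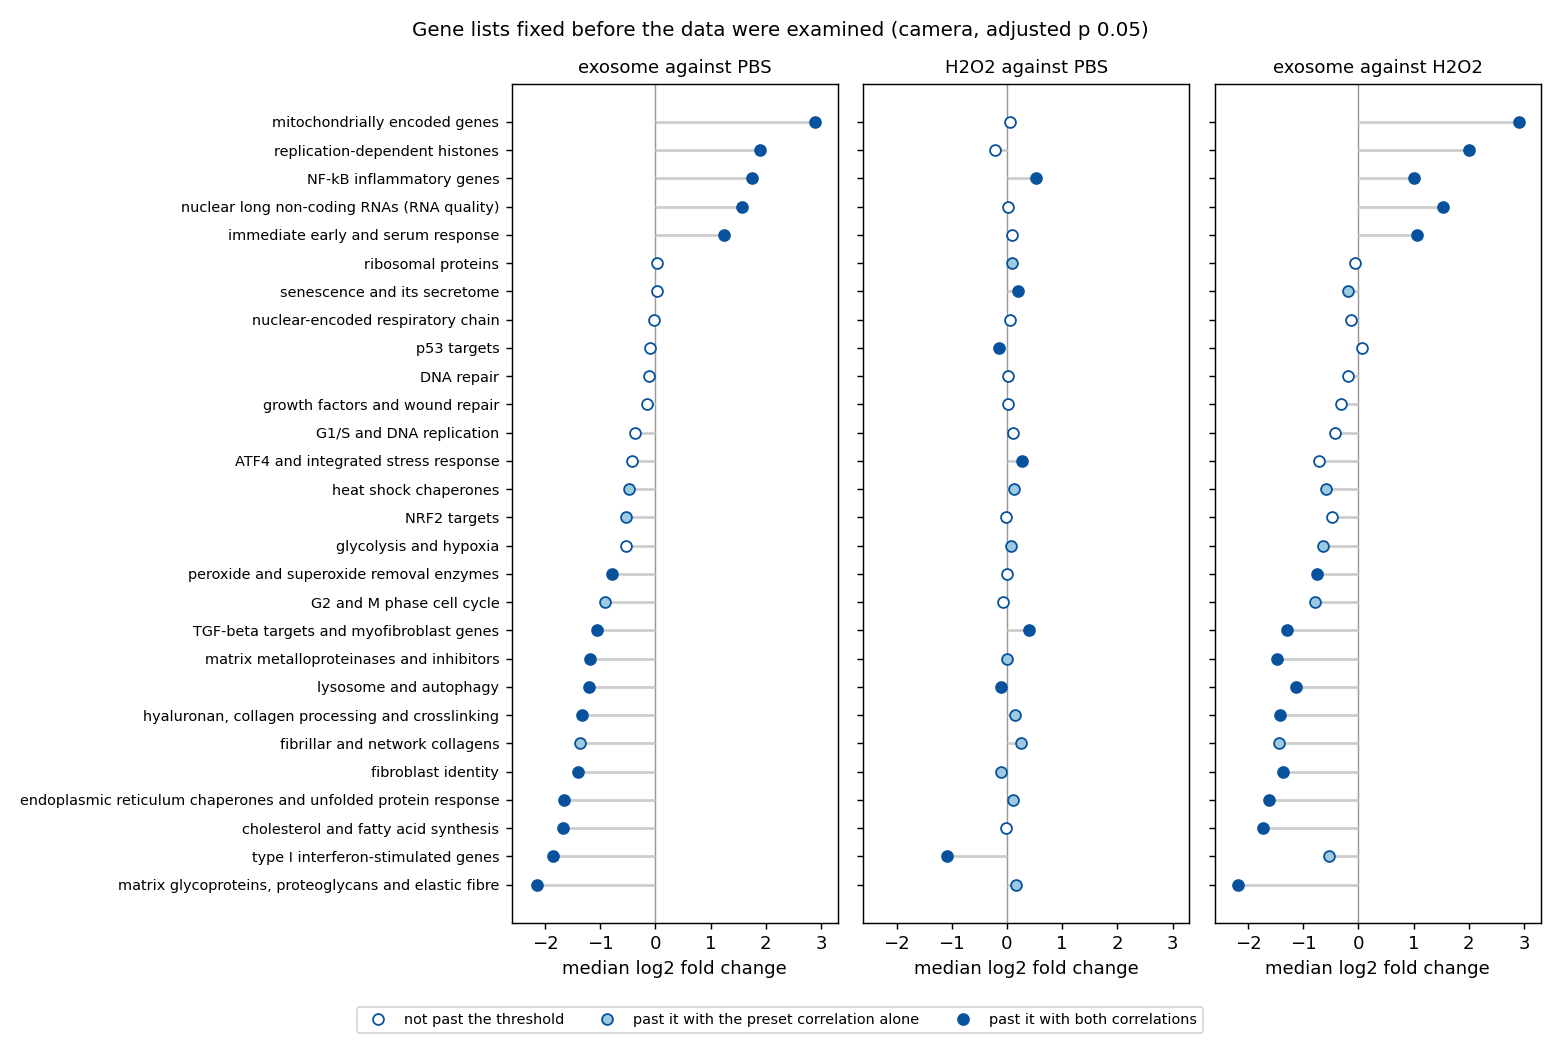
Median log2 fold change of the members of each gene list, with markers of other cells left out, in the 3 comparisons. Dark points passed camera at an adjusted p of 0.05 with the preset and the estimated correlation, pale points with the preset one alone and open points with neither; mitochondrially encoded genes lie at 2.89 and matrix glycoproteins at -2.15 in exosome against PBS.

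Among genes outside the lists that met the naming rule, the largest increases were in small and non-coding RNAs. VTRNA1-2, a vault RNA, had 6 counts over the PBS libraries and rose to 24.7 ± 4.38 CPM. SNORD3B-1, a U3 small nucleolar RNA with near-identical copies, rose from 3 counts over the PBS libraries to 14.7 ± 0.482 CPM, a ratio of 268.9 with a 95% counting interval of 91.6 to 1307. AC108134.2, a long non-coding RNA, rose from 2 counts by a ratio of 278.5 (76.7 to 2307), and AC015912.3, AC132192.2, AC109326.1 and the U2 spliceosomal copy RF00004 rose 69.01-fold, 40.5-fold, 39.7-fold and 51.9-fold. Of protein-coding genes ARC, an early gene best known in neurons, rose from 0.215 ± 0.134 to 17.9 ± 3.13 CPM. Besides LOX, DHCR7, COL12A1 and FN1, the largest decreases were in PCDHGA4, which shares exons with other protocadherins, EDIL3, CPD and MOXD1, which fell 11.9-fold, 11.2-fold, 9.55-fold and 9.52-fold.

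In total 12504 of 16627 genes passed in exosome against PBS with edgeR, 6459 higher and 6045 lower, and 3632 of the higher and 2273 of the lower changed at least 2-fold. Genes that rose had a median expression of 7.82 CPM and those that fell 39.6 CPM. Of 33 lists 19 passed, 5 up and 14 down, of which 15 also passed with an estimated correlation. With that correlation the camera adjusted p of these 15 ran from 7.67e-04 to 0.0189, each higher than with the preset one. Of all 16627 genes 12815 had no overlap between the libraries of the groups, which chance gives for 10% of genes. Log2 fold changes are relative to the scaling: the median over all genes was 0.05, and upper-quartile scaling moved it to 0.28, giving 7941 higher and 4712 lower. The balance turned with library totals as the scaling (6064 higher, 6398 lower) and with FPKM at a pseudocount of 1 (5677 and 5983) or 0.1 (5581 and 5993).

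The comparison of H2O2 with PBS asked what the oxidant did to the same fibroblasts. Type I interferon-stimulated genes were lower in the H2O2 libraries, and IFI44L, an antiviral gene (ENSG00000137959, chromosome 1, 78619922 to 78646145), fell 3.34-fold, from 196 ± 3.99 to 58.6 ± 1.43 CPM. ELN, elastin, the core of elastic fibres (ENSG00000049540, chromosome 7, 74027789 to 74069907), rose 4.32-fold, from 176 ± 6.4 to 761 ± 59.1 CPM. Most NF-kB inflammatory genes rose, CXCL8 going from 93.7 ± 3.81 to 318 ± 19.6 CPM, along with most TGF-beta targets and myofibroblast genes. Targets of NRF2 and peroxide-removing enzymes did not pass as lists with camera.

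Of 32 interferon-stimulated genes 28 fell and 4 did not pass in H2O2 against PBS (adjusted over the list alone, 29 fell), with a median log2 fold change of -1.09 (adjusted p = 3.52e-242, and adjusted p = 1.16e-06 with an estimated correlation). RSAD2 (viperin) fell 3.43-fold and CMPK2, which overlaps it on the other strand, 3.27-fold. IFIT1 and IFIT2, which bind viral RNA, fell 3.02-fold and 3.38-fold, MX2 fell 3.202-fold, and MX1 fell from 632 ± 18.6 to 236 ± 4.42 CPM. GBP4, an interferon-induced GTPase, and the annotated coding gene AC004551.1 fell 2.83-fold and 3.01-fold.

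Of 33 NF-kB inflammatory genes 22 rose, 1 fell and 10 did not pass (adjusted over the list alone, 23 rose and 1 fell; median 0.52, adjusted p = 3.45e-37). CXCL1 rose from 94.2 ± 3.03 to 271 ± 6.89 CPM, its close copy CXCL3 from 3.78 ± 0.371 to 13.1 ± 1.96 CPM, and CXCL6 from 47.3 ± 3.11 to 127 ± 5.29 CPM. Senescence genes, of which several are the same chemokines, rose in 15 of 33, 1 fell and 17 did not pass (adjusted over the list alone, 19 rose and 3 fell; adjusted p = 8.00e-20). TGF-beta targets and myofibroblast genes rose in 18 of 22 and 4 did not pass (adjusted over the list alone, 19 rose and 1 fell; median 0.40, adjusted p = 4.58e-25). TAGLN, a contractile protein, rose from 246 ± 6.44 to 396 ± 15.9 CPM and TPM1, tropomyosin, from 294 ± 10.9 to 525 ± 9.08 CPM. ATF4 and integrated stress response genes rose in 13 of 24, 1 fell and 10 did not pass (adjusted over the list alone, 13 and 1; adjusted p = 3.32e-15). SLC7A5, an amino acid transporter, rose from 183 ± 4.82 to 379.9 ± 11.3 CPM and CHAC1, which degrades glutathione, from 19.4 ± 0.248 to 36.8 ± 2.75 CPM.

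Matrix lists passed upward with the preset correlation alone. Of 20 collagens 11 rose, 2 fell and 7 did not pass (adjusted over the list alone, 12 rose and 2 fell; adjusted p = 1.45e-08, against adjusted p = 0.195 with an estimated correlation). COL1A1, a chain of type I collagen, rose from 8141 ± 346 to 11800 ± 727 CPM and COL4A1, of basement membranes, from 159.9 ± 8.99 to 256 ± 25.7 CPM. Matrix glycoproteins rose in 12 of 28, 3 fell and 13 did not pass (adjusted over the list alone, 13 rose and 5 fell; adjusted p = 1.41e-08, against adjusted p = 0.0956 with an estimated correlation). Hyaluronan and collagen processing genes rose in 9 of 20, 1 fell and 10 did not pass (adjusted over the list alone, 11 rose and 1 fell; adjusted p = 1.31e-05, against adjusted p = 0.0751 with an estimated correlation). TGM2, a transglutaminase, rose from 173 ± 3.03 to 328 ± 18.8 CPM. Metalloproteinases and inhibitors rose in 4 of 15 and 11 did not pass (adjusted over the list alone, 4 rose and 1 fell; median 0.0028, adjusted p = 0.04196, against adjusted p = 0.195 with an estimated correlation). This call was lost without PBS replicate 1 (adjusted p = 0.0537), PBS replicate 2 (0.107) or H2O2 replicate 3 (0.0582), with the replicate number as a block (0.0868), and with library totals as the scaling (0.0682), where the median turned to -0.03. TIMP3, an inhibitor, rose from 630.5 ± 7.8 to 869 ± 14.6 CPM.

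Heat shock chaperones rose in 6 of 17, 2 fell and 9 did not pass (adjusted over the list alone, 8 rose and 2 fell; adjusted p = 0.04196, against adjusted p = 0.281 with an estimated correlation). The call was lost without PBS replicate 1 (adjusted p = 0.0608) or H2O2 replicate 3 (0.0582) and with library totals as the scaling (adjusted p = 0.0733). HSPB1 rose from 245 ± 6.44 to 349 ± 25.5 CPM. Endoplasmic reticulum chaperones rose in 5 of 20 and 15 did not pass (adjusted over the list alone, 5 rose; adjusted p = 0.00481, against adjusted p = 0.0529 with an estimated correlation). Glycolysis and hypoxia genes rose in 9 of 29, 1 fell and 19 did not pass (adjusted over the list alone, 12 rose and 1 fell; adjusted p = 8.09e-04, against adjusted p = 0.0529 with an estimated correlation), with ANGPTL4 rising 3.32-fold. Ribosomal proteins rose in 8 of 47 and 39 did not pass (adjusted over the list alone, 9 rose; with library totals as the scaling, 3 rose; without PBS replicate 3, 1 rose; adjusted p = 9.81e-04, against adjusted p = 0.446 with an estimated correlation). p53 targets fell in 11 of 28, 1 rose and 16 did not pass (adjusted over the list alone, 14 fell and 3 rose; adjusted p = 8.09e-04). CCNG1 fell from 243 ± 7.48 to 180.5 ± 18.4 CPM and MDM2, which restrains p53, from 224 ± 5.16 to 192 ± 7.19 CPM. Lysosome and autophagy genes fell in 11 of 31, 2 rose and 18 did not pass (adjusted over the list alone, 14 fell and 3 rose; adjusted p = 8.09e-04), CTSK, cathepsin K, going from 2449 ± 67.6 to 1864 ± 61.95 CPM. Fibroblast identity genes fell in 5 of 18 and 13 did not pass (adjusted over the list alone, 5 fell; adjusted p = 0.00783, against adjusted p = 0.0956 with an estimated correlation), with PDGFRA going from 256 ± 7.83 to 179 ± 1.96 CPM.

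The other lists, those of the oxidant response among them, did not pass camera in H2O2 against PBS. With fry NRF2 targets (adjusted p = 0.00661), cholesterol and fatty acid synthesis (0.00182), G2 and M phase (0.0459) and histones (0.00182) passed downward and G1/S upward (0.00794). Of 27 NRF2 targets 3 rose and 7 fell (adjusted over the list alone, 4 and 7; adjusted p = 0.297), HMOX1 rising from 68.7 ± 2.29 to 114 ± 4.495 CPM and AKR1C1, of the similar AKR1C genes, falling from 140 ± 4.12 to 79.4 ± 6.87 CPM. Peroxide and superoxide removal enzymes rose in 3 of 21 and fell in 4 (adjusted over the list alone, 3 and 4; adjusted p = 0.927), with a median of 0.0062 (-0.02 with library totals as the scaling) and a mean of -0.02. PRDX6, a peroxiredoxin, rose from 266 ± 3.15 to 331 ± 4.66 CPM, and CAT fell from 90.7 ± 3.21 to 75.6 ± 2.85 CPM. Immediate early genes rose in 10 of 33 and fell in 5 (adjusted over the list alone, 11 and 7; with library totals as the scaling, 6 and 7; adjusted p = 0.301). Growth factors rose in 7 of 28 and fell in 6 (adjusted over the list alone, 9 and 8; with library totals as the scaling, 6 and 8; adjusted p = 0.4702), with a median of 0.02 and a mean of -0.0047; TGFA, a ligand of the EGF receptor, rose from 29.5 ± 2.48 to 56.4 ± 2.41 CPM. Cholesterol and fatty acid synthesis fell in 7 of 28 and rose in 2 (adjusted over the list alone, 8 and 4; adjusted p = 0.379). The list of G2 and M phase fell in 5 of 29 (adjusted over the list alone, the same; adjusted p = 0.0651), G1/S genes rose in 2 of 30 and fell in 1 (adjusted over the list alone, the same; adjusted p = 0.103), and DNA repair fell in 1 of 31 (adjusted over the list alone, 0; adjusted p = 0.927). Histones fell in 2 of 18 (adjusted over the list alone, 3; adjusted p = 0.05296), nuclear long non-coding RNAs rose in 2 of 14 and fell in 1 (adjusted over the list alone, the same; adjusted p = 0.806), and nuclear-encoded respiratory chain genes rose in 4 of 38 and fell in 1 (adjusted over the list alone, the same; adjusted p = 0.416). Histones passed downward with the replicate number as a block (adjusted p = 0.0141), without PBS replicate 2 (0.0312), PBS replicate 3 (0.0324) or exosome replicate 3 (0.0445), and with GC content and gene length corrected (0.0209). G2 and M phase passed downward with the block (adjusted p = 0.0155), without H2O2 replicate 3 (0.0206) and with library totals as the scaling (0.0472), and G1/S upward with the block (0.0433) and without H2O2 replicate 1 (0.0415). Mitochondrially encoded genes rose in 1 of 13 and fell in 2 (adjusted over the list alone, 2 and 3; adjusted p = 0.416), at a mitochondrial share of 4.25% ± 0.175 of the counts (exact permutation test against PBS, p = 0.2, two-sided). Markers of keratinocytes (adjusted p = 0.652), immune cells (adjusted p = 0.806), endothelium (adjusted p = 0.806) and pericytes (adjusted p = 0.3105) did not pass as lists, and 2 of the 4 melanocyte markers fell.

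**Figure D3:**
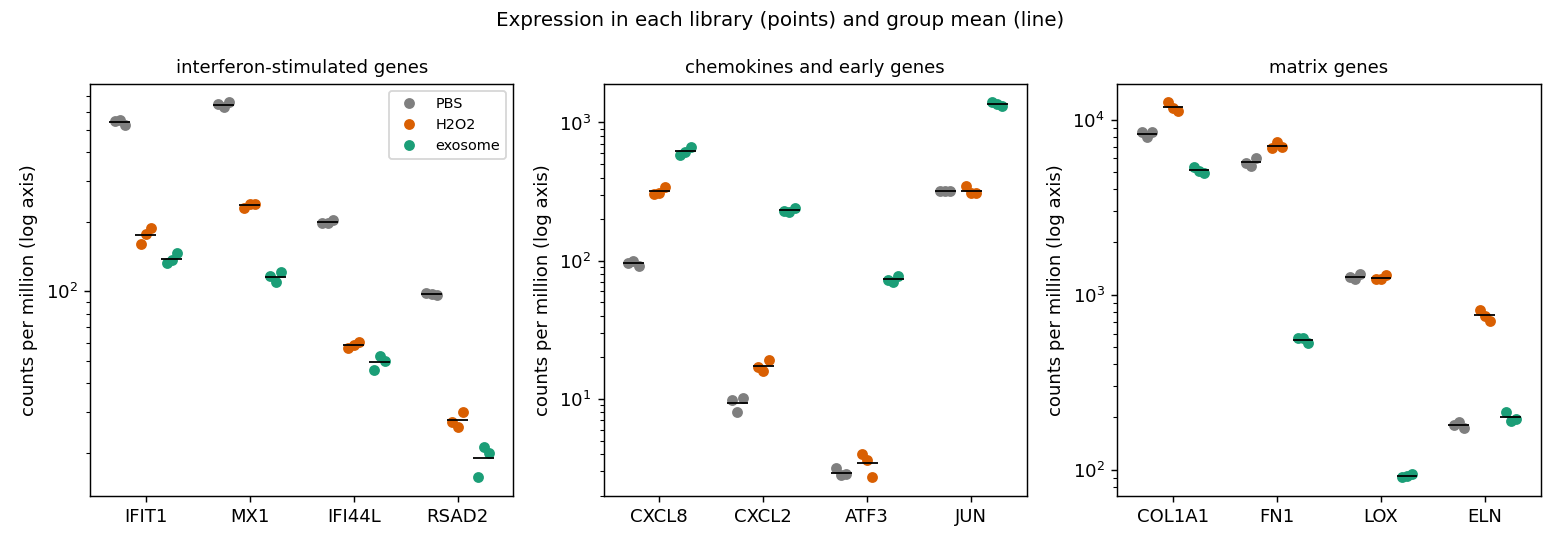
Expression of 12 genes in each library, in CPM without scaling factors (library total alone), on log axes. Points are libraries, lines are means of 3 libraries; the 4 interferon-stimulated genes drawn are highest in PBS, and elastin (ELN) is highest in H2O2.

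In H2O2 against PBS 2517 of 16627 genes passed, 1336 higher and 1181 lower, and 73 of the higher and 125 of the lower changed at least 2-fold. Outside the lists GAL, galanin, and the chemokine CXCL12 rose 2.54-fold and 2.42-fold. Of 33 lists 16 passed, 12 up and 4 down, of which 7 also passed with an estimated correlation. With that correlation the camera adjusted p of these 7 ran from 1.16e-06 to 0.0410, each higher than with the preset one. Of all 16627 genes 5190 had no overlap between the libraries of the groups (10% by chance). With library totals as the scaling 1046 genes were higher and 1469 lower.

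The comparison of exosome with H2O2 asked how these 2 groups differed directly. Whether the exosome cells had also received H2O2 was not stated, so it may not set the particles alone against the oxidant. Mitochondrial reads were higher and matrix genes lower in the exosome libraries: LOX fell 13.2-fold, from 1252 ± 30.2 to 94.96 ± 1.32 CPM, and FN1 12.5-fold, from 7099 ± 325 to 567 ± 23.96 CPM. Most NF-kB inflammatory genes and immediate early genes were higher, CXCL2 rising from 17.4 ± 1.51 to 239 ± 7.68 CPM and FOS from 63.4 ± 1.28 to 514 ± 16.9 CPM. The share of mitochondrial reads was 35.9% ± 0.321 in exosome and 4.25% ± 0.175 in H2O2, or 12.6 times as many relative to nuclear reads (exact permutation test, p = 0.1, two-sided, the smallest possible).

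Of the lists that rose in exosome against H2O2, mitochondrially encoded genes rose in 13 of 13 (adjusted p = 9.39e-46) and nuclear long non-coding RNAs in 12 of 14 with 2 lower (adjusted p = 1.74e-08). MT-CO2 rose from 4104 ± 77.2 to 32480 ± 418 CPM and SNHG1, a host of small nucleolar RNAs, from 16.8 ± 0.684 to 91.2 ± 2.61 CPM. Immediate early genes rose in 30 of 33, 1 fell and 2 did not pass (adjusted p = 3.01e-16), NF-kB genes rose in 22 of 33, 5 fell and 6 did not pass (adjusted p = 2.32e-07), and histones rose in 15 of 18, 1 fell and 2 did not pass (adjusted over the list alone, 16 rose and 1 fell; adjusted p = 1.17e-04). ZFP36, which destabilises cytokine mRNAs, rose from 43.6 ± 2.82 to 216 ± 12.01 CPM, while the complement gene C3 on the NF-kB list fell from 517 ± 20.4 to 171 ± 5.91 CPM.

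Of the lists that fell, matrix glycoproteins fell in 27 of 28 and rose in 1 (median -2.19, adjusted p = 3.37e-46). TNC fell 11.1-fold and FMOD, fibromodulin, 9.51-fold. Collagens fell in 17 of 20 and rose in 3 (adjusted p = 1.72e-12, against adjusted p = 0.0939 with an estimated correlation). Hyaluronan and collagen processing fell in 17 of 20, 1 rose and 2 did not pass (adjusted p = 3.77e-19), TGM2 going from 328 ± 18.8 to 40.7 ± 1.98 CPM. Metalloproteinases and inhibitors fell in 12 of 15 and 3 did not pass (adjusted p = 1.35e-10), and TGF-beta targets fell in 18 of 22, 2 rose and 2 did not pass (adjusted p = 1.72e-12). Fibroblast identity fell in 14 of 18, 2 rose and 2 did not pass (adjusted p = 1.96e-11). Endoplasmic reticulum chaperones fell in 18 of 20, 1 rose and 1 did not pass (adjusted p = 1.92e-16), cholesterol and fatty acid synthesis in 27 of 28 with 1 higher (adjusted p = 3.05e-17), and lysosome and autophagy in 26 of 31, with 2 higher and 3 not passing (adjusted p = 1.68e-15). Peroxide and superoxide removal enzymes fell in 14 of 21, 2 rose and 5 did not pass (adjusted p = 3.89e-04), PRDX6 going from 331 ± 4.66 to 137 ± 3.16 CPM.

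Further lists fell with the preset correlation alone. Interferon-stimulated genes fell in 22 of 32, 6 rose and 4 did not pass (adjusted p = 0.00137, against adjusted p = 0.0586 with an estimated correlation). G2 and M phase genes fell in 24 of 29, 2 rose and 3 did not pass (adjusted p = 1.66e-04, against adjusted p = 0.143 with an estimated correlation). Heat shock chaperones fell in 13 of 17, 1 rose and 3 did not pass (adjusted over the list alone, 14 fell and 1 rose; adjusted p = 0.00109, against adjusted p = 0.0621 with an estimated correlation). Glycolysis and hypoxia fell in 20 of 29, 8 rose and 1 did not pass (adjusted p = 0.00413, against adjusted p = 0.0586 with an estimated correlation), PKM, pyruvate kinase, going from 2887 ± 85.8 to 1041 ± 5.35 CPM. Senescence genes fell in 17 of 33, 14 rose and 2 did not pass (median -0.19, adjusted p = 0.0378, against adjusted p = 0.0723 with an estimated correlation). IGFBP3, which binds insulin-like growth factors, fell from 1680 ± 7.02 to 196 ± 1.76 CPM. The senescence call was lost without exosome replicate 1 (adjusted p = 0.0532), 2 (0.0630) or 3 (0.0560), and with upper-quartile scaling (0.126), where the median turned to 0.03.

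Lists that did not pass camera in exosome against H2O2 were NRF2 targets (8 of 27 rose, 16 fell, adjusted p = 0.0806), p53 targets (13 of 28 rose, 10 fell, adjusted p = 0.269) and ATF4 genes (6 of 24 rose, 13 fell, adjusted p = 0.242). With fry all 32 lists tested passed, among these p53 targets and immune markers upward and the other lists of this paragraph downward (adjusted p at most 0.00997). With GC content and gene length corrected NRF2 targets (adjusted p = 0.0374), ATF4 genes (0.0445) and markers of pericytes (0.0479) passed downward. SLC7A5 fell from 379.9 ± 11.3 to 131 ± 5.52 CPM and SLC7A11 from 112 ± 5.06 to 33 ± 2.07 CPM. G1/S genes fell in 18 of 30 and rose in 5 (adjusted p = 0.0766), the nuclear-encoded respiratory chain fell in 17 of 38 and rose in 9 (adjusted p = 0.5201), and ribosomal proteins fell in 21 of 47 and rose in 14 (adjusted p = 0.599). DNA repair fell in 14 of 31 and rose in 10 (adjusted p = 0.565), and growth factors fell in 13 of 28 and rose in 10 (adjusted p = 0.1896). With upper-quartile scaling more members rose than fell among the nuclear-encoded respiratory chain (16 and 8), ribosomal proteins (23 and 11) and DNA repair (11 and 10). For markers of keratinocytes (adjusted p = 0.921) the median of 0.03 and the mean of -0.27 differed in sign, and markers of immune cells (adjusted p = 0.378), endothelium (adjusted p = 0.599) and pericytes (adjusted p = 0.0892) did not pass either. Counts adjusted over the list alone were otherwise those given.

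Outside the lists HIST1H4E, a histone copy, rose from 0.881 ± 0.209 to 61.5 ± 3.76 CPM and BCAT1, of branched-chain amino acid metabolism, fell from 52.9 ± 2.39 to 5.32 ± 1.22 CPM; ARC, VTRNA1-2, AC015912.3, AC109326.1, RF00004, AC108134.2 and SNORD3B-1 (3 counts over the H2O2 libraries, ratio 261.0, interval 88.9 to 1269) were again among the largest increases. In exosome against H2O2 12440 of 16627 genes passed, 6442 higher and 5998 lower, and 3657 of the higher and 2211 of the lower changed at least 2-fold. Of 33 lists 20 passed, 5 up and 15 down, of which 14 also passed with an estimated correlation. With that correlation the camera adjusted p of these 14 ran from 0.00139 to 0.0148, each higher than with the preset one. Of all 16627 genes 12567 had no overlap between the libraries of the groups (10% by chance). Upper-quartile scaling moved the median of all genes from 0.06 to 0.28 and gave 7866 higher and 4700 lower, while FPKM at a pseudocount of 1 gave 5633 and 5958.

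The responses to exosome and to H2O2, each against PBS, overlapped more than independent lists would among genes that fell, but not among genes that rose. Whether the exosome cells had also received H2O2 was not stated, so these may not be responses to 2 separate treatments. Interferon-stimulated genes fell in both, MX1 with log2 fold changes of -2.41 with exosome and -1.42 with H2O2, and CXCL8 and HMOX1 rose in both. Of the genes on matrix lists, COL8A1, LTBP2 and TIMP3 rose with H2O2 and fell with exosome. In all 1330 genes passed in both comparisons in the same direction, 514 higher and 816 lower, and 807 passed in opposite directions. Independent lists of these sizes would give 519 genes higher in both, 429.4 lower in both and 944.5 opposite. Those numbers leave out what the shared PBS libraries add. They also leave out expression level. Against PBS, genes that rose with exosome had a median of 7.82 CPM and those that fell 39.6 CPM. With H2O2 these medians were 57.6 and 40.8 CPM, nearer to the genes that fell with exosome. How far this accounts for the excess among genes that fell was not tested. Because both comparisons use the same PBS libraries, 20 simulated pairs of unchanged groups with shared controls were run, and these gave a mean of 0.15 shared genes. The simulated groups held no changed genes, so this mean is no reference for the 1330. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.184 where shared controls alone gave 0.482. Their covariance was 0.110 where shared controls alone gave 0.0282. Changed genes widen the spread that a correlation is divided by, so 0.482 from unchanged groups is no reference for 0.184. The covariance is not divided by that spread, and it shows only that shared controls in unchanged groups gave less.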

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

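The mitochondrial and the GC and length settings were added after the result was seen; all other settings here were planned. Genes changed in exosome against PBS numbered 12504, with 5905 of them at least 2-fold, and lay between 10024 and 13517 under the other settings with all libraries. In H2O2 against PBS 2517 changed, 198 at least 2-fold; FPKM with no filter on low values gave 1115, the cause of which was not tested, and the other settings with all libraries 1704 to 2912. In exosome against H2O2 12440 changed, 5868 at least 2-fold, and 9928 to 13527 under the other settings with all libraries. The 2-fold counts are smaller by construction. Leaving out 1 library gave 12097 to 13053, 1829 to 2798 and 12047 to 12781 genes, 18 to 20, 14 to 17 and 19 to 20 lists, and 952 to 1603 shared genes against 1330. For H2O2 against PBS 7 of 16 lists passed with an estimated correlation, the cause of which was not tested, and fry passed 28 lists against 19 in exosome against PBS, 21 against 16 in H2O2 against PBS and 32 against 20 in exosome against H2O2; it does not compare a list with other genes.

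Pairing by replicate number was at most weak: 9 pairs of the same number had correlations of -0.006 to 0.095, none above 0.1. Libraries matched their own number best in 16 of 18 cases, so a weak effect shared by number is not excluded. With the replicate number as a block 12492, 2738 and 12424 genes, 19, 18 and 20 lists and 1464 shared genes passed. Of 3329 values of named genes under alternatives 3312 kept direction and side of the threshold in exosome against PBS and 17 lost the call; these were 2585 of 2727 in H2O2 against PBS, with 138 lost and 4 gained, and 3236 of 3242 in exosome against H2O2, with 6 lost. No named gene or list that had passed also passed in the other direction, but the balance of higher and lower genes turned with library totals in exosome against PBS (6064 and 6398) and H2O2 against PBS (1046 and 1469). The block ended the call of metalloproteinases in H2O2 against PBS and added G2 and M phase, G1/S and histones. Each alternative in the plan was run. Depth limits genes with few counts: PBS libraries held 2 to 6 counts of AC108134.2, SNORD3B-1 and VTRNA1-2.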

Other observations

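Of the tests below, the evenness of the added mitochondrial reads, the range of the list medians, the settings without mitochondrial genes and with GC content and gene length corrected, and the matched median beside a matched mean of segments were chosen after the results were seen. The comparison of reads gained by olfactory receptor and by mitochondrial genes was not set beforehand. Of long non-coding genes 1462 of 2139 rose with exosome against PBS, and of protein-coding genes 4303 of 12958. Long non-coding genes had a median log2 fold change of 1.35 against PBS and 1.39 against H2O2, where protein-coding genes had -0.11 and -0.11. Features with at least 1 count numbered 26726 ± 604 in exosome libraries, 23457 ± 126 in PBS and 23219 ± 297 in H2O2 (SD, n = 3) and exosome libraries had the lowest mean total count. The 20 most abundant features took 37.6% of exosome counts, 11.4% of PBS and 11.97% of H2O2. Relative to library totals without scaling factors, mitochondrial ribosomal RNA MT-RNR1 was 16.7 times and MT-RNR2 12.03 times as high as in PBS, and the 13 mRNAs between 6.11 and 19.1 times.

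Splits of 3 against 3 libraries number 10, too few for a share under 0.05. Every split but the real one mixes the groups, so that the difference between the groups counts as spread within them. Low gene counts in the mixed splits therefore follow from the design and lend the real split no support. Mixed splits also keep part of the group difference in the list means, so the list counts decide nothing either. The real split gave 12504 genes in exosome against PBS where the highest other split gave 0, so that 1 split of 10 reached it; for H2O2 against PBS these were 2517, 2 and 1, and for exosome against H2O2 12440, 0 and 1. For lists the real split gave 19 and the highest other 21, with 4 of 10 splits as high, in exosome against PBS; 16, 10 and 1 in H2O2 against PBS; and 20, 20 and 3 in exosome against H2O2. Of 50 drawn splits of the 9 libraries into 3 groups, 1, the real one, gave as many as 1330 shared genes, and the highest other gave 11. Splits that mix the groups pass few genes in either comparison, so few can be shared. This count therefore does not tell whether the 2 responses are alike.

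Mitochondrial RNA was higher in every exosome library than in any PBS or H2O2 library. DNA in the libraries, which would add reads evenly, is argued against as the whole cause. Reads added per kilobase differed 75.6-fold between the 15 mitochondrial mRNA and rRNA genes, and 8.43-fold without the 5 that overlap a neighbour. An even part from DNA beneath this uneven rise is not excluded. Olfactory receptor genes, silent in fibroblasts, had a read in 30.1% of cases in pooled exosome libraries and 9.04% in PBS, between the bounds of 20% and 50% set for it. Their reads per kilobase were 4.41 times those in PBS, under the bound of 5 set with it, so the test as set decides nothing. The reads they gained, 0.0120 CPM per kilobase, were far below the 665 of MT-ATP8, the fewest added to a mitochondrial gene, and the 5963 of MT-ND5, the fewest without an overlap. That comparison was not set beforehand and does not measure mitochondrial DNA, whose copies may differ in number. Nuclear DNA may be present in a small amount. Total RNA in place of poly(A) RNA cannot be told apart from a change in the cells: RN7SK, RN7SL1, RN7SL2, RMRP and RPPH1 summed to at most 33.3 CPM in an exosome library, under the bound of 100, but 4 of the 5 are 0 in all 9 libraries. The rises of VTRNA1-2, U2 and U3 copies, histones and mitochondrial rRNA go with that explanation. The rise was not limited to these, as mitochondrial mRNAs such as MT-CO1 (6.87 times) and MT-CO3 (6.59 times) rose too. RN7SL1, the 1 of the 5 with counts, had a mean of only 26.9 CPM in exosome, 15.5 in H2O2 and 6.95 in PBS. A response of the cells stays open as well, since no absolute amount of RNA was measured.

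The falls of matrix, sterol, chaperone and lysosome genes and the rises of NF-kB and immediate early genes in the exosome libraries might follow from mitochondrial reads taking 35.9% of the counts. Such reads lower nuclear genes alike, which is argued against as the whole cause by the medians of all 31 nuclear lists tested, whether or not they passed, whose interquartile range was 1.19 on the log2 scale against PBS and 1.11 against H2O2, where H2O2 against PBS gave 0.17; the test first set, on calls with mitochondrial genes left out before scaling, decides nothing, since that moves nuclear lists nearly alike. With GC content and gene length corrected 100% of the lists past the threshold over both exosome comparisons kept call and direction, which argues against these as the whole cause. RNA of another cell type is argued against by its markers: among members under 5 CPM in PBS the highest mean over the 5 lists was 1.13 CPM, in immune cells, whose highest gene, CCR7, had 19.9 CPM against 1.64. Total RNA in place of poly(A) RNA, left open above for the mitochondrial reads, was not tested for these list directions. It stays open here too, since the labels do not say whether all libraries were prepared in the same way. The share of long non-coding reads, 1.53% in exosome and 0.710% in PBS, cannot part it from a change in the cells. Loss or decay of cytoplasmic mRNA stays open. On the nuclear long non-coding list 12 of 14 RNAs rose, and NORAD, a cytoplasmic one, was among the 2 that fell. The list cannot decide this, since where its members lie in these cells was not measured. Hosts of small nucleolar RNAs such as SNHG1 and SNHG12 were among those that rose. An effect of the particles on transcription stays open beside loss of mRNA and a different preparation of the libraries.

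Interferon-stimulated genes were higher in PBS than in H2O2 and exosome libraries. Immune cells in the PBS libraries are argued against, as PTPRC, CD74, HLA-DRA, LYZ and TYROBP summed to at most 0.951 CPM there. The pattern did not rest on 1 PBS library, since the list median of -1.09 in H2O2 against PBS moved no farther than to -1.08 when any was left out, and with GC content and gene length corrected it was -1.05. An interferon signal set off in the PBS cultures, or lowered by both treatments, may lie behind it, and no test here parts these.

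A hypothesis was that messages for proteins made at the endoplasmic reticulum, which carry a membrane or signal segment, fell more than others with exosome. Over 4881 genes with a predicted segment and 8001 without, matched on expression, length and GC content, the median log2 fold change differed by -0.41 and the mean by -0.43 (95% interval -0.47 to -0.39, permutation test p = 1e-05, the smallest that 100000 permutations can give); without matching, 53.3% of the former fell and 38.2% of the latter. The matched median lies between the bounds of -0.5 and -0.2 set for it, so it leaves the hypothesis open; in H2O2 against PBS the median difference was -0.0314 (mean -0.02, permutation test p = 0.0008), above the bound of -0.1. Genes are not independent, so the p-values cover only the spread across genes.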
